A study of Arabidopsis thaliana with 4 samples.

How the data were processed

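Total RNA of apetala1 and wild-type inflorescences was hybridised together on 4 two-colour long-oligonucleotide arrays, named sets 1 to 4 and used as replicates 1 to 4. Per the labels, channel 1 held apetala1 RNA on sets 1 and 3 and wild-type RNA on sets 2 and 4. The labels state that the authors processed and normalized the data by a published method. The steps, the software, the background correction and the dyes are not given in the sources used here.

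The deposited values are log2 ratios of the channels of each array. The base follows from the values, since every column stops at plus and minus the log2 of 100, or 6.64. Which channel is the numerator stays unknown. The deposited columns had medians over probes of -0.00, 0.06, 0.04 and 0.03 on sets 1 to 4, so they are not centred exactly on 0, and no further centring was applied in the reported fit. The number of value columns that belonged to no sample was 0.

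The table had 26933 rows, of which 26474 were probes and 424 were empty spots. Rows named as calibration, ratio, utility or negative controls and rows named atc were left out of the tests. Rows whose names begin with GP were kept as probes, although the sources used here do not say what they are. Probes were named through the platform annotation given for them and through the gene table of assembly TAIR10.1, used only for names and for which genes neighbour each other. That annotation gave 1 gene for 5784 probes, several for 7497 and none listed for 13193, and 5756 of the single-gene probes matched a locus. No gene was named from a probe with several genes. AT2G11270 and AT4G07670 had 17 and 16 probes, which points to uncertain assignments there. In 247 genes with exactly 2 probes, the mean ratios of both probes correlated across genes at r = 0.41 and rho = 0.50 (permutation p = 0.0001 for r, the smallest that 10000 permutations can give), and 178 had the same sign.

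The orientation of the arrays departed from the plan. The plan, fixed before the data were examined, turned sets 2 and 4 if the median Pearson correlation between arrays of opposite channel order was below 0 as deposited. Over all deposited values that median was 0.33, so the plan applied literally turned no array and called 152 features. The values at the limits had not been foreseen. A value at a limit gives only a bound, and on 3 of the 4 arrays the median empty spot, which carries no probe, lay at the upper limit. The 2765 limit values of probes were therefore treated as not measured, after the correlations and the empty spots had been seen. On the values left, the median was -0.15 and the same rule turned sets 2 and 4. A planned check on the features in the top and bottom 10 percent of the mean gave 0.07, above 0, but choosing features by an extreme mean as deposited favours those that run alike as deposited, so this value decides nothing. A planned Spearman correlation gave -0.20. Everything reported as positive or negative depends on this choice.

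Probes of one gene were averaged per array. Features with a value on at least 3 arrays were tested, which gave 25415 features, 5265 of them named by 1 gene, and left out 718. The mean log2 ratio of each feature was compared with 0, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3 and Benjamini-Hochberg adjustment. Features with an adjusted p below 0.05 are called. If sets are technical dye exchanges of the same extracts, the arrays are not separate replicates and these p-values are too small.

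Gene lists and families were tested with the camera method on the moderated statistics, with a preset inter-gene correlation of 0.01, for lists with at least 3 and families with at least 10 measured genes. Families had been planned from gene descriptions, but the words were matched to the symbols and synonyms of the gene table, so family counts are of matched genes and not of all measured members. Lists were written from memory before the data were examined; the symbol written for 309 of the 326 entries was found at its locus in the gene table, and the others were used by locus. The genes named in the text are AP1 and the measured floral MADS-box genes, the 3 called members of each other list with the largest absolute ratio or else its 1 largest member, and the 10 named features with the largest and the 10 with the smallest ratio among called features with the same sign on every array. Genes named outside this rule are said to have been chosen after their values were seen, and this also holds for UF3GT, ATA20, UGT73D1, UGT74D1, AT4G28085 and AT5G37730.

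The fit was tested on simulated data with independent normal noise at the moderated spread of the real features, in which 200 of 25415 features were changed. It called 0 of 70 features changed by 0.5 on the log2 scale, 19 of 62 changed by 1 and 64 of 68 changed by 2, with 4 false calls. The simulation held no channel bias and no difference in spread between arrays, so these shares need not hold for the real arrays. Alternatives fixed beforehand were a channel order term, centring, scaling, quantile normalization, other filters, robust eBayes, array weights, single probes, a threshold of 0.01, an estimated correlation, fry and leaving out each replicate. Windows of 1000 and 5000 locus numbers around AP1 were fixed beforehand too. Alternatives added after the data were seen were keeping the limit values, turning no array, counting probes with several genes, and other filters when a replicate was left out.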

Results

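RNA from inflorescences of apetala1 mutant and wild-type Arabidopsis thaliana plants was compared on 4 two-colour oligonucleotide arrays. APETALA1 (AP1) is a MADS-box transcription factor needed for floral meristem identity and for sepals and petals. Each array received both RNAs, and the channels were exchanged on sets 2 and 4 relative to sets 1 and 3. The arrays held 26474 probes, of which 26367, 26436, 26404 and 26408 had a value on sets 1, 2, 3 and 4. The number of arrays, 4, limits the precision of each ratio. The labels do not say whether the sets came from separate plants, so p-values measure only the spread between these arrays, which may be technical. The question the design poses is which transcripts differ in abundance between inflorescences with and without AP1 function.

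The direction of the ratio stayed unknown. The labels name neither dye nor numerator, and the list of petal genes chosen to anchor the direction had 1 measured gene, too few to test. Values are therefore given as positive or negative in the sign of sets 1 and 3, and neither side is called higher in the mutant. The signs also rest on turning sets 2 and 4, a choice made after the values were seen, and the calls below were lost or replaced where it was not made.

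In the comparison of apetala1 with wild type, 12 genes with a probe of their own differed, all on the positive side. The largest ratio was that of AT2G30810, a member of the gibberellin-regulated GASA family, at a log2 ratio of 2.50 ± 0.68 (SD, n = 4; limma adjusted p = 0.0446). AT5G47350 followed at 2.41 ± 0.61 (adjusted p = 0.0394) and AT1G57980 at 2.02 ± 0.36 (adjusted p = 0.0266). AT4G19380, of the long-chain fatty alcohol oxidase family, had a log2 ratio of 1.96 ± 0.42 (adjusted p = 0.0357). AT5G45950, of the GDSL lipase family, had 1.86 ± 0.34 (adjusted p = 0.0299). UGT85A5, a UDP-glycosyltransferase, had 1.84 ± 0.45 (adjusted p = 0.0424). The ratios of AT1G20180, AT5G57760, AT5G58570 and AT4G32460, the last of the DUF642 family of cell wall proteins, were 1.49 ± 0.30, 1.48 ± 0.16, 1.3 ± 0.08 and 1.25 ± 0.20. AT4G28085 and AT5G37730 completed the 12 genes at 1.19 ± 0.21 and 1.11 ± 0.11. Each of these genes had the same sign on all 4 arrays once sets 2 and 4 were turned.

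**Figure D1:**
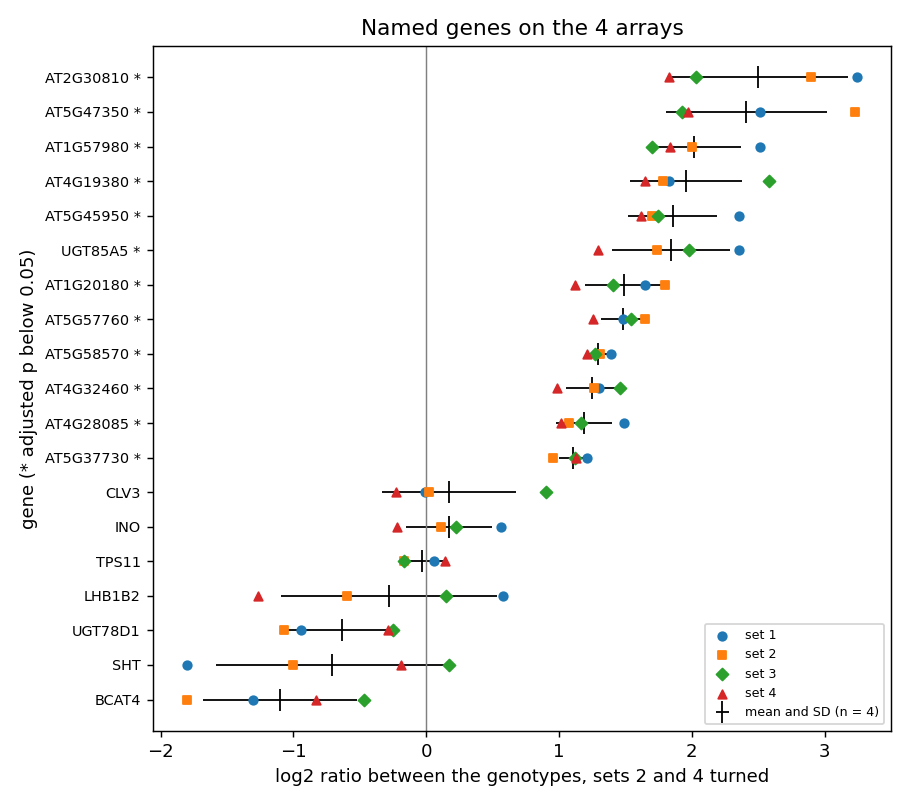
Log2 ratios (x axis) of the named genes (y axis) on each of the 4 arrays after sets 2 and 4 were turned, with the mean as a vertical tick and the SD as a horizontal bar (n = 4). The 12 genes marked with an asterisk passed the adjusted p threshold and lie above 0 on every array, from a mean of 1.11 for AT5G37730 to 2.50 for AT2G30810, while CLV3, INO, TPS11, LHB1B2 and SHT have arrays on both sides of 0.

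Over all 25415 features tested, 56 passed an adjusted p of 0.05 in limma, 50 positive and 6 negative. Their absolute log2 ratios ran from 1.07 to 3.41, with a median of 1.85. Of these features, 10 were probes assigned to several genes and 34 were probes without a listed gene, so 44 cannot be named. The 6 negative features were among those 44. So were GP005A3, GP005A4 and GP007B6, rows whose nature is not given. At an unadjusted p under 0.05 there were 4148 features, 2333 positive and 1815 negative. This count rests on 2 choices made after the values were seen, namely that values at the deposited limits were left out and that sets 2 and 4 were turned. The orientation rule fixed beforehand, applied to all deposited values, turned no array. That fit called 152 features, 152 positive and 0 negative, sharing 0 with the 56. It kept the limit values, and 86 probes lay at the upper limit on all 4 arrays. With limit values left out, the fit with no array turned called 0 features. Of the 4 arrays, leaving out replicate 1 gave 0 calls and leaving out replicate 2 gave 1, and a term for channel order left 1. These fits also had fewer residual degrees of freedom than the 3 of the main fit. Fewer calls there need not mean an array or channel effect.

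Other genes at least 2-fold to one side on all 4 arrays did not pass the adjusted threshold, and they were picked out after their values were seen. On the positive side these were AT5G53810 at 2.96 ± 1.25 (limma adjusted p = 0.0901), AT3G55870 at 2.35 ± 0.79 (0.0640), AT4G15750 at 2.3 ± 0.89 (0.0787), AT3G25810, a terpene synthase, at 2.09 ± 0.74 (0.0703) and AT4G12530 at 2.02 ± 0.64 (0.0612). On the negative side AT2G02750 had -2.03 ± 0.70 (0.0671). Without replicate 4, AT5G53810 (limma adjusted p = 0.0224) and AT3G25810 (0.0430) passed, and none of these genes did without another replicate. With unnamed features included, 73 lay at least 2-fold on the positive side on all 4 arrays and 14 on the negative side. With no array turned these counts were 1 and 0, and with limit values kept and no array turned they were 209 and 0.

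The gene lists fixed beforehand were thinly covered by probes assigned to 1 gene alone. Of 15 lists, 8 had no measured gene, among them the floral organ identity MADS-box genes with AP1 itself, so the mutated gene could not serve as a check of the labels. The other lists without a measured gene were the flowering-time regulators, mature pollen, trichome, cell division, jasmonate, cytokinin and stress genes. After the data were seen, probes whose genes all belong to one list were counted as well, which left 5 lists with no feature. The flowering-time list then had 1 feature, at a log2 ratio of -1.84, which was not called. Mature pollen genes had 3 features (median 0.29, camera adjusted p = 0.181). Carpel and ovule genes had 7 (median -0.10, camera adjusted p = 0.37). None of the 5 lists tested in this way passed. Of the 16 list genes measured, 0 passed the adjusted threshold over all features in limma.

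The aliphatic glucosinolate list had 3 measured genes, 1 positive and 2 negative, with a median log2 ratio of -0.35 (camera adjusted p = 0.208 over the 3 lists tested, and 0.928 with an estimated correlation). BCAT4, which acts in methionine chain elongation, had -1.10 ± 0.58 (SD, n = 4; limma adjusted p = 0.136), below 0 on all 4 arrays, and was the 1 gene of this list that passed when adjusted over the list alone. The list passed the threshold without replicate 3 (adjusted p = 0.0231), with a median of -0.51.

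The flavonoid and anthocyanin list had 3 measured genes that went both ways, and its median was -0.15 (camera adjusted p = 0.916, and 0.928 with an estimated correlation). UGT78D1, a flavonol rhamnosyltransferase, had -0.64 ± 0.43 (limma adjusted p = 0.214). UF3GT, a glycosyltransferase of anthocyanins, had 0.46 ± 0.19 (limma adjusted p = 0.198). These 2 genes passed when adjusted over the list alone. Adjusting over 3 genes, here and in the glucosinolate list, is a mild correction, and 4148 of the 25415 features had an unadjusted limma p under 0.05. The sign of this list's median turned without replicate 1 or without replicate 2.

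The photosynthesis list had 5 measured genes, 4 positive and 1 negative, with a median of 0.16 and a mean of 0.06 (camera adjusted p = 0.780, and 0.928 with an estimated correlation). Adjusted over the list alone, 0 of the 5 passed. Its member with the largest absolute ratio, the light-harvesting gene LHB1B2, had -0.28 ± 0.81 (limma adjusted p = 0.686), and its arrays lay on both sides of 0.

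The remaining 4 lists had 1 or 2 measured genes and were not tested as lists on these genes alone. Values for their leading members were 0.17 ± 0.50 for the stem cell signal CLV3, -0.03 ± 0.16 for the sesquiterpene synthase gene TPS11 (AT5G44630), -0.71 ± 0.88 for SHT, a tapetal acyltransferase, and 0.17 ± 0.32 for the ovule gene INO. None of these 4 genes passed in limma, with adjusted p from 0.360 for SHT to 0.913 for TPS11. The second tapetum gene, ATA20, had -0.30 ± 0.45. The 3 probes of INO were averaged and disagreed, with mean ratios of 0.56, -0.48 and 0.43.

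Gene families were formed from words in the symbols and synonyms of the gene table. This misses members named by locus or by a short symbol, and can take in genes that only share the word. AT5G45950 and LHB1B2, for example, were in none of the families. Of 26 families formed in this way, 1 had 10 or more matched genes. This was the UDP-glycosyltransferase family, with 17 genes, 11 positive and 6 negative, a median log2 ratio of 0.14 and 1 called gene, UGT85A5. As a family it did not stand apart from the other features (camera p = 0.151, and 0.363 with an estimated correlation). Within it, UGT73D1 had -0.88 ± 0.82 and UGT74D1 had 0.44 ± 0.32, neither of which passed in limma (adjusted p = 0.260 for each).

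The deposited values of sets 2 and 4 ran against those of sets 1 and 3 by Pearson correlation only where values at the limits were left out, and by Spearman correlation with them kept as well (median -0.12). Before turning, the Pearson correlations across features between arrays of opposite channel order were -0.38, -0.22, -0.07 and -0.07, with a median of -0.15, when values at the limits were left out. Arrays of the same order correlated at 0.34 and 0.24. These correlations run across features, which are not independent replicates. With the limit values kept, the median for opposite order was 0.33. In the fit with a channel order term, made with limit values left out, limma called 0 features for that term. The same fit called 1 feature for the ratio between the genotypes, so 0 calls is a weak check. For it, 1156 features had an unadjusted p under 0.05, against 1271 expected by chance. These counts cannot show a channel bias held in the limit values that were left out.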

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

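The tests of the limit values and of dim spots in this part were chosen after the values were seen, and the test of centring was set before its result was seen. Of 31 results checked for 1 array standing apart from the other 3, 4 did so by Dixon's ratio, and chance picks out about 1 in 20. The median of the empty spots was 0.28 on set 1, against 6.64 on each of sets 2, 3 and 4. Those 3 medians are tied at the upper limit, which fixes the ratio at 1 whatever the gap, so this result does not count as evidence that set 1 stands apart. The share of empty spots at the upper limit was 19.4% on set 1, against 64.7%, 59.2% and 58.9%. For AT5G53810 the log2 ratio of 1.09 on set 4 stood apart, and for AT3G25810 the 3.20 on set 4 did.

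Empty spots, which enter no comparison, gave large values. At the upper limit were 77 empty spots on set 1, 273 on set 2, 247 on set 3 and 241 on set 4. Signal near background in 1 channel, whatever RNA it holds, is a candidate explanation for limit values, since empty spots were at the upper limit at least 16.5 times as often as probes on every array. Whether a difference between apetala1 and wild type adds to the limit values of probes depends on the orientation. Of 583 probes at a limit on arrays of both channel orders, 10, or 1.72%, turned their sign with the channel order. Another 563, or 96.6%, kept one sign. If the deposited ratios follow the channel order, as the reported fit takes them to, a genotype difference would turn the sign. Under that orientation the values argue against it as the main source of limit values in these 583 probes. A kept sign is what a genotype difference would give if the columns already shared one orientation. Probes at a limit in 1 channel order only are not covered, and for them the question stays open. Empty spots, which carry no probe, were also at the upper limit on arrays of both channel orders. A kept sign can therefore arise without a genotype difference, and the 563 probes do not by themselves point to one. Why set 1 differs stays open too.

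Most calls were positive, 50 of 56. Arrays lying off 0 do not account for this, because after centring each array 91.1% of the calls were positive. The split was more even in other fits, with 114 positive and 26 negative calls among features measured on all 4 arrays, 87 and 22 with robust eBayes, and 27 and 11 without replicate 4. A bias of dim spots towards positive deposited values, larger on sets 1 and 3, would by itself give negative values on the turned arrays. All 56 calls had the same sign on every array, but a mean so far from 0 relative to its spread over 4 arrays practically requires that. Features moved by such a bias alone would have mixed signs after turning and would not be called. The shared sign is therefore no test of this bias. Whether such a bias adds to some of the positive calls stays open. The empty spots had a median of -0.68 after turning, but their median lay at the upper limit on 3 of the 4 arrays, so a larger bias could not show there and the value decides nothing. Other technical sources of an uneven split were not tested, and unequal numbers of transcripts differing between the genotypes stay open as an untested biological explanation.

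Chance was checked by giving the 4 arrays each of the 8 possible sign patterns. The channel order of the labels was the 1 pattern that called 56 features or more, and the highest count of the others was 2, with limit values left out, a choice made after the values were seen. With limit values kept, the fit with no array turned called 152 and the fit with sets 2 and 4 turned called 1; the other patterns were not run that way. With 8 patterns a share under 0.05 cannot be reached, and the orientation itself was settled on the same values.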

How the results depend on the processing

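Alternatives that keep the limit values, leave the arrays unturned or change the filter of a fit without a replicate were chosen after the data were seen. The count of 56 features depends strongly on the processing. It was 1 with a channel order term, 1 at a threshold of 0.01, 11 with quantile normalization (11 positive, 0 negative, against 50 and 6), 109 with robust eBayes and 140 with features measured on all 4 arrays only. Keeping the limit values gave 1 with arrays turned and 152 with no array turned; leaving them out and turning no array gave 0 (852 at an unadjusted p under 0.05). Leaving out each replicate gave 0 to 38 calls: 0, 1, 30 and 38 without replicates 1, 2, 3 and 4 where all 3 arrays left had a value, 0, 0, 8 and 2 over the features tested on 4 arrays, and 0, 0, 1 and 2 where 2 values sufficed. Centring, scaling, array weights, single probes and a filter of 2 arrays gave 40 to 56, but scaling to equal spread shared 24 of its 40 calls with the 56. The 30 and 38 calls without replicates 3 and 4 shared 23 and 21 with them. Among the 12 called genes, 12 lost the call with the channel order term, 11 with quantile normalization, 12 each without replicates 1 and 2 and 10 each without replicates 3 and 4. With the channel order term their ratios were the same by construction, since each had a value on all 4 arrays and the channel orders are balanced. Without 1 replicate the widest range of the ratio among them was 2.25 to 2.73 (AT2G30810) and the narrowest 1.26 to 1.32 (AT5G58570). The cause of these changes was not tested. Fits with the channel order term or without 1 replicate had fewer residual degrees of freedom than the 3 of the main fit. That by itself makes a call harder to reach.

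The median correlation between arrays of opposite channel order changed sign, from -0.15 to 0.0698 in the features with the highest and lowest means, and to 0.33 with limit values kept; it was -0.20 by Spearman correlation, and -0.12 by Spearman with limit values kept. Without 1 replicate in turn, the flavonoid median ran from -0.48 to 0.0783 and turned positive without replicate 1 and without replicate 2 (0.0278), the glucosinolate median ran from -0.51 to -0.21 and passed the threshold once, and the photosynthesis and UDP-glycosyltransferase medians ran from 0.00 to 0.25 and from 0.07 to 0.20. Ratios of CLV3 (-0.0727 to 0.31), TPS11 (-0.0921 to 0.0108) and LHB1B2 (-0.57 to 0.0439) changed sign in such fits. The planned direction anchor, a camera test of the petal list, could not be run under any setting. That list had 1 measured gene, and 2 features when probes with several genes of the list counted. With limit values left out, the channel order effect stayed at 0 calls after centring. Signal over background is not given in the values used here, so the dimness of single probes is unknown.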

Other observations

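The test of the petal probes in this part was chosen after their values were seen, and the test of genes near AP1 was set before. When probes with several genes of one family were counted as well, 4 of the 26 families formed from words in symbols and synonyms had 10 or more features. Expansins, which loosen cell walls, then had 14 features, of which 9 were positive, with a median log2 ratio of 0.32. Their limma camera adjusted p was 0.0948 (0.0282 unadjusted). The word histone, which can also match genes that are not histones, gave 11 features, of which 2 were positive, with a median of -0.16. Their limma camera adjusted p was 0.0948 (0.0474 unadjusted). Cytochromes P450 had 10 features and UDP-glycosyltransferases 29, with adjusted p of 0.347 and 0.156. None of the 4 families passed after adjustment.

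A first hypothesis was that positive values mean lower in apetala1, whose flowers lack or reduce petals. The 6 probes assigned to at least 1 petal gene had a median log2 ratio of -0.10 and ran from -0.41 to 0.91, with 2 above 0 (exact sign test, two-sided p = 0.688). They leave the direction undecided.

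A second hypothesis was that expression differences linked to the mutated locus add called genes near AP1. Of 74 named genes within 2000 locus numbers of AP1, 0 were called by limma, against 12 of 5191 elsewhere (Fisher's exact test, one-sided p = 1). At an unadjusted p under 0.05 there were 15 near AP1 and 756 elsewhere (Fisher's exact test, one-sided p = 0.115). Within 1000 locus numbers there were 8 of 33 genes, against 763 of 5232 elsewhere (Fisher's exact test, one-sided p = 0.0987). Within 5000 there were 38 of 207, against 733 of 5058 (Fisher's exact test, one-sided p = 0.0776). Both of these windows held 0 called genes. With 12 called genes in all, the test leaves this open.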
